A study of Homo sapiens with 6 samples.

How the data were processed

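RNA sequencing libraries were made from T24 cells, a human bladder carcinoma line, with a control hairpin (shNC-1) or a hairpin against DLGAP5 (shDLGAP5-1), 3 libraries each. Per the labels' protocols, total RNA was extracted with a column kit and went into a kit for mRNA libraries. Samples were grouped by their titles, which also number them 1 to 3. The columns of the control libraries carry the letters NC and the number of their sample. The other 3 columns carry a construct number in place of a group name, and were given to shDLGAP5-1 because it is the only other group, so the level of DLGAP5 is reported first as a check of the labels.

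The authors deposited 1 table of normalized values for 58825 genes, with Ensembl identifiers, symbols and coordinates, which the values show to be FPKM (fragments per kilobase of transcript, divided by library size). Its header names no unit. The values are not whole, sum to different totals per library (413001 to 487559), and in single-exon genes of low level pile up at a value inversely proportional to gene length. The aligner, the quantifier, the annotation and the use of strand are not given in the sources used here. Of the identifiers, 58552 (99.5%) are in GENCODE release 29, and 51024 of these (87.1%) have the same GRCh38 coordinates, so coordinates are given in that build. FPKM divide by length and by total, so a library with more short transcripts or with a few abundant transcripts shifts all other genes, and overlapping genes, host genes of microRNAs and close paralogs can share reads. Totals were 413001, 415099 and 435077 FPKM in shNC-1 replicates 1 to 3 and 487559, 447253 and 431491 in shDLGAP5-1 replicates 1 to 3, of which mitochondrial genes took 8.35% to 11.2%. An exact 0 may be a failed estimate, so such a gene is said to be listed at 0.

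Depth was estimated from the smallest repeated step of low single-exon genes. The estimates, 13700000 to 27500000 fragments, are approximate: of the values checked, 16.5% to 28.3% per library came out whole within 0.05, so fragments were not recovered as counts and no count test was run. Genes with at least 1 FPKM numbered 12177 to 12279 in the shNC-1 libraries and 12711 to 13216 in the shDLGAP5-1 libraries. The deeper libraries measure low genes with less error. Squared differences between libraries of a group had a median 2.12 times that of counting noise for shNC-1 replicates 1 and 2. For the other pairs of libraries it was 8.38 to 16.0 times, with counts taken from the approximate depths. This does not show that they came from separate cultures, since repeat preparations of 1 culture can also exceed counting noise; they were kept as separate samples because the titles list them so.

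Choices of tests, gene lists and genes to name were made before the data were examined, except where chosen afterwards as stated. The planned main test was a count test, with limma-trend as the test for a table without counts; the table held FPKM, so the latter was used. Genes with at least 1 FPKM in at least 3 libraries (12714) were tested with limma 3.58.1 in R 4.3.3, with a trended variance, on log2(FPKM + 1), with group as the only term and Benjamini-Hochberg adjusted p under 0.05 as the threshold. Fold changes are on that scale, which understates the change of low genes. Levels are means ± SD over 3 libraries. Exact permutation tests of FPKM were two-sided.

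Lists of genes, 36 in number, were written by hand. They cover the E2F family, S phase, recombination, histones, mitosis, DLGAP5 partners, p53, apoptosis, interferon, antigen presentation, cytokines, signalling, adhesion, metabolism, stress, ribosomes and other cell types or states. The 33 with at least 3 tested members were compared with other genes by camera, with a preset inter-gene correlation of 0.01 and adjustment over these lists; the fibroblast, leukocyte and endothelial lists had too few. Camera called 12 lists, of which 1, interferon response, held with an estimated correlation. Histone, TGF-beta and amino acid gene symbols that had changed were matched through the reference. The genes named were DLGAP5, E2F1, USP11 and their families, the 10 largest rises and 10 largest falls among genes that passed with a mean of at least 5 FPKM, no overlap between groups and a gene symbol that is not a pseudogene or clone name, and up to 4 members of each list with the smallest p. The planned minimum of 5 CPM was applied as 5 FPKM. All other genes named were chosen after their values were seen, and some genes that the rule names are not reported here.

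Gene lengths are those of the longest transcript in GENCODE release 29, which 12701 of the tested genes (99.9%) have. The length trend of a library is a lowess curve, with a span of 0.3, of its deviation from the gene mean. Alternatives were a pseudocount of 0.1, no filter, a filter of 5 FPKM, other scalings (same total, median ratio, quantile), removal of the length trend, a replicate block, a robust variance prior, limma's treat with a log2 fold change of 0.5, an absolute log2 fold change of at least 1, leaving out each library, leaving out shDLGAP5-1 replicates 1 and 3 together, and for lists an estimated correlation, fry, and members with a mean of at least 5 FPKM.

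The gene-wise test was tested on simulated data for the comparison of the groups over 12714 genes, with 200 changed genes in each of 5 runs. It recovered 8.1% of genes changed by a log2 fold of 0.5, 59.1% at 1 and 89.4% at 2, and 4.4% of calls were false. The data gave 3155 calls, and the adjustment of p is stricter where fewer genes change. These shares therefore do not measure recovery in the data. In 20 runs with 1 shifted list of 40 genes, camera called the shifted list in 20 and 3 of 640 other lists. The simulated genes were drawn independently, so these runs do not test camera on lists whose members are correlated. A simulated length slope of −0.17 became −0.004 after removal, over 12714 genes. Depth was recovered with an error of 0.0% at 5 simulated depths over 12619 genes. The simulated values were whole multiples of the step, unlike most values in the data, so this does not measure the accuracy of the depths given here. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9 was used for depths and figures.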

Results

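Messenger RNA was measured by sequencing in T24 cells, an established line from a human bladder carcinoma. 3 libraries carried a control hairpin, shNC-1, and 3 carried a hairpin against DLGAP5, shDLGAP5-1. DLGAP5 encodes a protein that binds spindle microtubules during mitosis, and the series concerns a circuit of DLGAP5 and E2F1, a transcription factor for entry into S phase. The single comparison asks which transcripts differed between the hairpins, and whether E2F1 was among them. Depth was estimated from the smallest steps in the values at 21600000, 27500000 and 24400000 fragments in shNC-1 replicates 1 to 3, and at 13700000, 13800000 and 18300000 fragments in shDLGAP5-1 replicates 1 to 3. Across genes, log2 levels correlated at 0.959 to 0.985 within groups and at 0.927 to 0.952 between them, and the first principal component, with 54.7% of the variance, separated the groups. The labels do not say that samples came from separate cultures, so p-values measure only the spread between these samples, which may be technical.

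DLGAP5 was lower in every shDLGAP5-1 library than in every shNC-1 library. It stood at 32.98, 32.7 and 29.7 FPKM in shNC-1 replicates 1 to 3 and at 5.03, 4.0 and 7.51 FPKM in shDLGAP5-1 replicates 1 to 3, a mean of 31.8 ± 1.83 against 5.51 ± 1.80 (SD, n = 3 each), or 82.7% lower. Its log2 fold change was −2.37 (standard error 0.19, limma adjusted p = 0.000894). An exact two-sided permutation test of the FPKM gave p = 0.1, the smallest that 3 against 3 libraries allow. The gene (ENSG00000126787) lies on the minus strand of chromosome 14 from 55148112 to 55191608, in GRCh38 coordinates.

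E2F1 showed no difference larger than the spread between libraries. Its level was 32.1 ± 2.41 FPKM in shNC-1 and 33.8 ± 1.87 FPKM in shDLGAP5-1 (SD, n = 3 each), with a log2 fold change of 0.07 (standard error 0.10, limma adjusted p = 0.647; exact permutation p = 0.4). The 95% interval of the ratio ran from 0.887 to 1.24, and the sign of the estimate flipped to −0.04 with columns scaled to the same total, −0.05 with median-ratio scaling and −0.01 after removal of a length trend. These settings also lowered the median of all genes. Relative to that median the E2F1 log2 fold change was 0.038 as reported and 0.025, 0.025 and 0.001 in these settings, with no change of sign. USP11, a deubiquitinase, stood at 21.9 ± 1.26 FPKM in shNC-1 and 18.3 ± 3.48 FPKM in shDLGAP5-1 (log2 fold change −0.26, limma adjusted p = 0.254). The 95% interval of the ratio was 0.651 to 1.07. All shDLGAP5-1 libraries (14.31, 20.53 and 20.12 FPKM) lay under all shNC-1 libraries (21.9, 23.13 and 20.61 FPKM). Its exact permutation p was therefore 0.1, the smallest possible, although 20.53 lay only just under 20.61 FPKM. Of 15 tested genes of the E2F, DLGAP and retinoblastoma list, which also held USP11, TFDP1, the dimer partner of E2F proteins, fell by 0.40 on the log2 scale (adjusted p = 0.0297) and E2F5, an E2F that binds pocket proteins, rose by 0.51 (adjusted p = 0.0444). Neither passed when adjusted over the list alone (adjusted p = 0.0779 for both, 0 higher and 0 lower), both calls were lost in leave-one-out fits, and that of E2F5 was also lost under each other scaling. The list median was 0.07, the value of E2F1 itself, and so it also turned to −0.04, −0.05 and −0.01 with same-total scaling, median-ratio scaling and the length trend removed. Relative to the median of all genes it did not change sign in these settings. The list test by camera, whose direction was down, gave an adjusted p of 0.991. E2F1 (ENSG00000101412) lies on chromosome 20 from 33675477 to 33686385 and USP11 (ENSG00000102226) on chromosome X from 47232690 to 47248328.

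**Figure D1:**
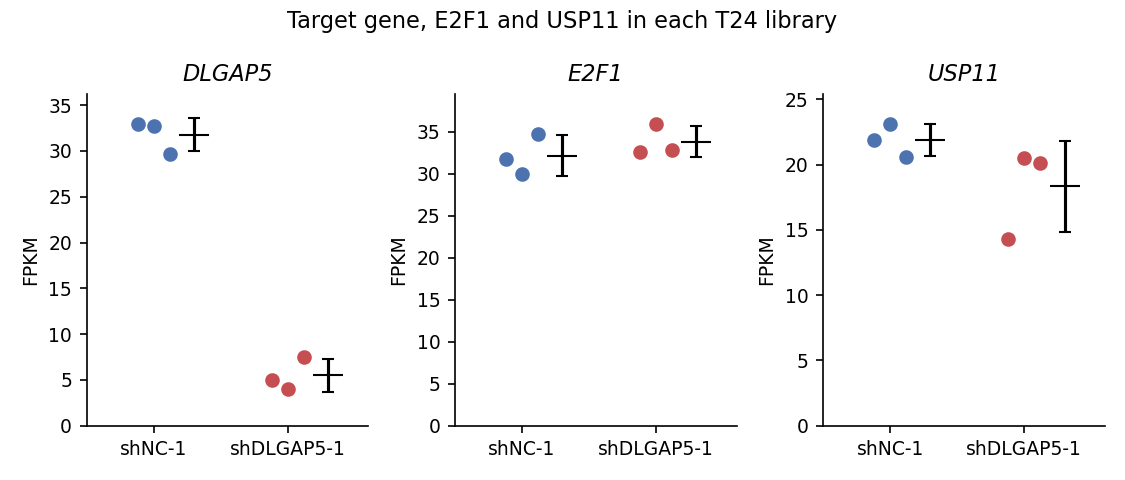
FPKM of DLGAP5, E2F1 and USP11 in each library; points are libraries, and crosses with bars are means ± SD of 3 libraries per group. The shDLGAP5-1 libraries lie at 4.0 to 7.51 FPKM for DLGAP5, under all shNC-1 libraries, while those for E2F1 overlap the controls.

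RARRES3, IFITM1, CFB, ASS1 and HLA-B were among the largest rises, and KRTAP2-3, TXNRD1, ZBTB38 and CXCL3 among the largest falls. RARRES3, a phospholipase that is induced by retinoids, went from 1.41 ± 0.325 to 16.3 ± 4.54 FPKM (SD, n = 3 each; log2 fold change 2.82). ASS1, the arginine synthesis enzyme argininosuccinate synthase, rose by 2.73, TXNIP, an inhibitor of thioredoxin, by 2.60, and DHRS3, a retinal reductase, by 2.16. CFB, complement factor B, rose by 2.78, but overlaps C2 in the annotation, as TXNRD1 does EID3 and ZBTB38 does PXYLP1, so reads can be shared; DHRS3, ESM1, UCA1 and OAS1 overlap other entries too. TXNRD1, thioredoxin reductase of the cytosol, fell from 531.2 ± 53.7 to 83.0 ± 26.7 FPKM, a log2 fold change of −2.71. KRTAP2-3, a keratin-associated protein gene, had a log2 fold change of −2.93, ZBTB38, a zinc finger protein that binds methylated DNA, −2.27, ESM1, a secreted proteoglycan, −2.19, UCA1, a noncoding RNA known from bladder carcinoma, −2.17, and ADAMTS1, a secreted metalloprotease, −1.86. MIR3615, a microRNA gene within SLC9A3R1, rose by 4.28 and MIR22, within its host gene MIR22HG, fell by 2.83; reads of host and microRNA cannot be told apart, so both are uncertain. SENP3-EIF4A1, a read-through of SENP3 and EIF4A1 and uncertain for that reason, stood at 26.6, 48.5 and 24.8 FPKM in shNC-1 and was listed at 0, 0 and 11.1 FPKM in shDLGAP5-1, a log2 fold change of −3.84 that lost its call in leave-one-out fits. Of 12714 tested genes, 3155 changed, 1944 higher and 1211 lower (61.6% higher), and 584 of them had an absolute log2 fold change of at least 1, 406 higher and 178 lower.

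The split of these calls depended on how the libraries were scaled and on the filter of low values. With a filter of 5 FPKM and the scaling as reported, 52% of calls were higher. With columns scaled to the same total, 47.8% of calls were higher, with median-ratio scaling 41.8%, with quantile normalization 50.8%, and after removal of the length trend 50%. Median-ratio scaling moved the median log2 fold change of all genes, 0.03 as reported, by −0.11. Same-total scaling moved it by −0.0957, so a small list median can turn negative through this common shift alone. Relative to that median, DLGAP5 had a log2 fold change of −2.40 as reported and −2.40 with median-ratio scaling, and E2F1 0.04 and 0.02. The call count was smaller in some fits without 1 library, which also hold fewer samples. It was 1511 without shNC-1 replicate 1, 1335 without shNC-1 replicate 2, 1937 without shNC-1 replicate 3 and 2056 without shDLGAP5-1 replicate 2. The highest count of a leave-one-out fit was 3141. In 5578 genes (43.9%) all libraries of one group lay above all of the other, where chance gives 10%.

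Interferon response genes rose together in shDLGAP5-1 cells. Of 34 tested members 30 rose and 0 fell, with a median log2 fold change of 1.26, and the list median per library lay at 1.24, 1.29 and 1.21 above the control mean in shDLGAP5-1 replicates 1 to 3. OASL, an antiviral relative of the oligoadenylate synthetases, went from 3.79 ± 0.566 to 26.2 ± 3.84 FPKM (SD, n = 3 each), and DDX58, the RNA sensor RIG-I, from 10.7 ± 0.177 to 35.3 ± 1.20 FPKM. DDX60, an RNA helicase induced by interferon, rose by 1.96, OAS1, which makes oligoadenylates that activate RNase L, by 2.24, and HERC5, the ligase for ISG15, by 1.47. IFITM1, a membrane protein against virus entry, rose by 3.19, with an annotation that overlaps its paralog IFITM2. Among the 4 members that did not pass were HERC6 (0.34), OAS3 (0.41) and SAMD9L (0.64), named after their values were seen. The count adjusted over the list alone was 32 higher and 0 lower. The camera test gave an adjusted p of 7.66e-18, and it held with an estimated correlation (adjusted p = 0.0165), which it did for no other list. White blood cell transcripts were present in shDLGAP5-1 replicate 3, with LYZ, lysozyme, at 686 FPKM against 0.598 to 21.1 FPKM elsewhere; without that library 29 interferon genes rose.

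Genes of MHC class I antigen presentation were also higher. Of 16 members 10 rose and 1 fell, with a median log2 fold change of 0.97. HLA-B rose from 20.9 ± 2.11 to 141.6 ± 3.99 FPKM (SD, n = 3 each; log2 fold change 2.71) and HLA-F by 1.47; these class I heavy chain genes are close paralogs, HLA-B and HLA-C overlap in the table, and the split of reads between them is uncertain. PSMB9, a subunit of the immunoproteasome, rose by 1.22. The member that fell was TAP2, a subunit of the peptide transporter, at −0.66, named after its value was seen, a call lost without shNC-1 replicate 1 or 2 or shDLGAP5-1 replicate 2. Adjusted over the list alone, 11 were higher and 2 lower. The camera test gave an adjusted p of 0.000107, and an adjusted p of 0.218 with an estimated correlation. Without shDLGAP5-1 replicate 3, the library with white blood cell transcripts, 11 rose.

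Genes of mitosis and G2/M were lower in shDLGAP5-1 cells. Of 65 tested members 50 fell and 0 rose, with a median log2 fold change of −0.62. CDC20, the activator of the anaphase-promoting complex, went from 128 ± 5.36 to 56.5 ± 3.13 FPKM (SD, n = 3 each), and CCNB1, cyclin B1, from 121 ± 7.87 to 57.8 ± 2.46 FPKM. PLK1, a mitotic kinase, had a log2 fold change of −1.27 and KIF20A, a kinesin of cytokinesis, −1.12. Of 13 genes whose proteins work with DLGAP5 at the spindle, 7 of them shared with the mitosis list, 8 fell and 0 rose (median −0.56). TPX2, a microtubule nucleation factor, fell from 125 ± 0.844 to 61.1 ± 8.09 FPKM, AURKA, the Aurora A kinase, by 1.07 on the log2 scale, and KPNB1, importin beta, by 0.92. When adjusted over the list alone, 56 mitosis genes and 9 spindle genes were lower and 0 higher. Camera gave adjusted p of 2.51e-20 and 1.54e-05, and with an estimated correlation both lists had an adjusted p of 0.0904. The counts were smaller in some fits without 1 library, which also hold fewer samples. Mitosis falls numbered 25 without shNC-1 replicate 1, 26 without shNC-1 replicate 2 and 32 without shDLGAP5-1 replicate 2. Spindle falls numbered 4, 3 and 5 there, and 5 also without shNC-1 replicate 3. Without shDLGAP5-1 replicate 1 or 3, 47 and 48 mitosis genes and 8 and 7 spindle genes fell. Over all leave-one-out fits the mitosis median stayed between −0.61 and −0.69, with a camera adjusted p of at most 4.97e-18.

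S-phase genes, the targets of E2F proteins in DNA replication, moved both ways. Of 57 tested members 7 rose and 6 fell, both before and when adjusted over the list alone, and the median log2 fold change was −0.10. CDT1, which loads the replicative helicase, rose from 35.5 ± 1.34 to 59.6 ± 3.73 FPKM (SD, n = 3 each) and MSH6, a mismatch repair protein, by 0.85. RRM1, the large subunit of ribonucleotide reductase, fell from 79.7 ± 2.21 to 50.1 ± 5.44 FPKM, and GINS3, part of the replicative helicase complex, had a log2 fold change of −0.55, a call lost without shNC-1 replicate 1 or 2. Among 26 homologous recombination genes MND1, a recombination factor known from meiosis, rose by 0.50, also lost without shNC-1 replicate 1 or 2, and 0 fell; adjusted over the list alone 0 were higher and 0 lower, and the median was −0.09. Among 12 replication-dependent histone genes 0 passed over all genes or adjusted over the list alone, and the median was −0.08, which turned to 0.11 without shNC-1 replicate 2. The camera adjusted p was 0.216 for S phase, 0.330 for recombination and 0.568 for histones. With median-ratio scaling the S-phase calls were 3 higher and 10 lower and the recombination calls 1 higher and 3 lower. The 14 calls of the S-phase and recombination lists fell to 3 without shNC-1 replicate 1 or 2, to 8 without shNC-1 replicate 3 and to 7 without shDLGAP5-1 replicate 2.

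**Figure D2:**
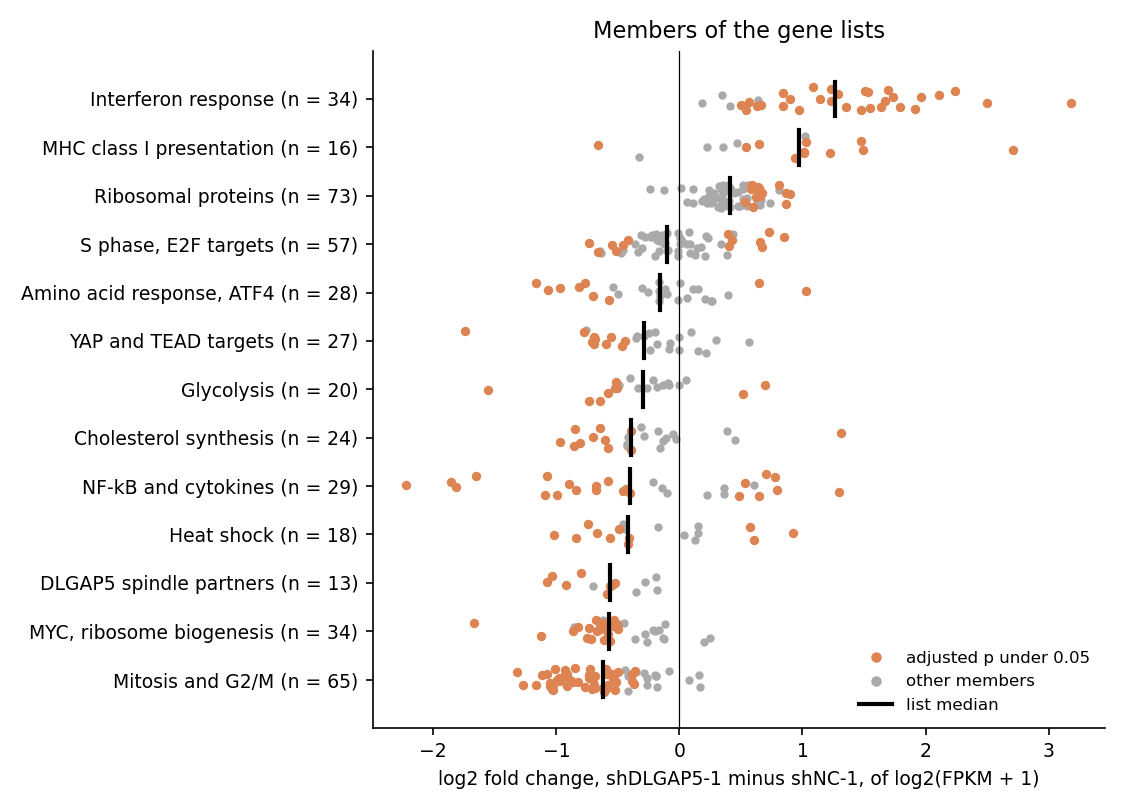
Log2 fold change (shDLGAP5-1 minus shNC-1, of log2(FPKM + 1)) of each tested member of 13 gene lists; orange points have an adjusted p under 0.05, grey points do not, and black bars mark list medians. Interferon response genes have a median of 1.26, S-phase genes −0.10 and mitosis genes −0.62.

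Genes of ribosome assembly and MYC response were lower, and ribosomal protein genes higher. Of 34 tested ribosome biogenesis and MYC target genes 20 fell and 0 rose, with a median log2 fold change of −0.57. ODC1, the first enzyme of polyamine synthesis, went from 145 ± 6.08 to 45.0 ± 3.36 FPKM (SD, n = 3 each), and NCL, nucleolin, from 275 ± 7.87 to 167 ± 12.2 FPKM. BOP1, a processing factor of the large subunit, had a log2 fold change of −0.87 and LYAR, a nucleolar protein, −0.82. Of 73 ribosomal protein genes 15 rose and 0 fell, with a median of 0.41; RPL28 rose by 0.87, a call lost without shNC-1 replicate 1 or 2. With p adjusted over the list alone, 22 biogenesis genes were lower and 0 higher, and 0 ribosomal protein genes were higher or lower. Camera gave adjusted p of 8.75e-11 and 1.47e-06, with an estimated correlation adjusted p of 0.0904 and 0.709. The biogenesis count was 13 without shNC-1 replicate 2. The ribosomal protein count was 0 without shNC-1 replicate 1 or 2, 7 without shDLGAP5-1 replicate 1 or 2, 2 with median-ratio scaling, 1 with the replicate block and 0 with the block after the length trend was removed, and the median was 0.20 with quantile normalization. By their longest annotated transcripts, ribosomal protein genes had a median length of 1857 bases. The transcripts expressed can be shorter, so removal of the length trend may be incomplete for them. Short transcripts were higher in shDLGAP5-1 replicate 1 than in the other libraries. Many ribosomal protein genes have pseudogenes that can share their reads.

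Genes of the NF-kB list changed in both directions, with more falls than rises, and targets of YAP and TEAD were lower. Of 29 tested members 15 fell and 7 rose, with a median log2 fold change of −0.40. CXCL2, a chemokine for neutrophils, went from 182.5 ± 4.95 to 51.1 ± 4.11 FPKM (SD, n = 3 each), and IL1B, interleukin 1 beta, from 900.0 ± 24.7 to 421.5 ± 8.93 FPKM. CXCL3 had a log2 fold change of −2.22 and CXCL5 −1.65; these chemokine genes are paralogs. Of 27 targets of YAP and TEAD 10 fell and 0 rose (median −0.29), among them IGFBP3, which binds insulin-like growth factors, at −1.74, and CCN2, a matricellular protein, from 55.8 ± 1.17 to 34.2 ± 2.07 FPKM. Adjusted over the list alone, 9 NF-kB genes were higher and 15 lower, and 1 YAP target was higher and 11 lower. Camera gave adjusted p of 0.0130 and 0.000167, with an estimated correlation adjusted p of 0.171 and 0.408, and the NF-kB call was lost without shDLGAP5-1 replicate 3 (adjusted p = 0.0722), with median-ratio scaling (0.0546), with quantile normalization (0.0759) and with a filter of 5 FPKM (0.0732). The NF-kB rises numbered 3 without shNC-1 replicate 2 and 4 without shDLGAP5-1 replicate 2, and 4 against 15 falls with columns scaled to the same total; 6 YAP targets fell without shNC-1 replicate 1 or 2.

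Sterol synthesis, glycolysis, heat shock and amino acid response genes were lower as lists. Of 24 cholesterol synthesis genes 10 fell and 1 rose (median −0.39): NSDHL, a sterol dehydrogenase, went from 31.3 ± 2.37 to 17.4 ± 0.430 FPKM (SD, n = 3 each), and TM7SF2, a sterol reductase, rose by 1.31. Of 20 glycolysis genes 7 fell and 2 rose (median −0.30), among them HK2, hexokinase of the first step, at −1.56, and PGK1, phosphoglycerate kinase, from 193 ± 4.39 to 129 ± 3.86 FPKM. Of 18 heat shock genes 8 fell and 3 rose (median −0.41); STIP1, a cochaperone, had a log2 fold change of −1.02 and HSPA1A, an inducible chaperone with a nearly identical copy, rose by 0.93. Of 28 amino acid response genes 7 fell and 2 rose (median −0.16); TRIB3, a pseudokinase, was at −1.07 and PHGDH, the first enzyme of serine synthesis, rose by 1.03. Adjusted over the list alone, 1 cholesterol gene was higher and 13 lower, 2 glycolysis genes higher and 7 lower, 3 heat shock genes higher and 10 lower, and 2 amino acid response genes higher and 7 lower. Camera gave adjusted p of 0.000251, 0.00342, 0.0436 and 0.0480, and with an estimated correlation adjusted p of 0.0904, 0.340, 0.303 and 0.408. The heat shock and amino acid calls were lost without shNC-1 replicate 3 (adjusted p = 0.0705 and 0.0694), without shDLGAP5-1 replicate 3 (0.1002 and 0.153), with the replicate block (0.0543 and 0.0519), with median-ratio scaling (0.0546 and 0.0508), with quantile normalization (0.0901 and 0.310) and with a filter of 5 FPKM (0.1004 and 0.179). Without shNC-1 replicate 1, 2 or 3 the falls numbered 4, 4 and 3 for cholesterol, 4, 3 and 4 for glycolysis and 4, 3 and 5 for heat shock, and 5 and 4 cholesterol genes fell without shDLGAP5-1 replicate 1 or 2; glycolysis rises numbered 0, 0 and 1 without shNC-1 replicate 1, 2 or 3 and 1 without shDLGAP5-1 replicate 1 or 2, amino acid rises numbered 1 without shNC-1 replicate 1 or 2, and cholesterol rises 2 without shDLGAP5-1 replicate 3. Leaving out shDLGAP5-1 replicates 1 and 3 together, the 2 libraries with the strongest length trend and with white blood cell transcripts, leaves 1 shDLGAP5-1 library that is assumed to vary like the controls; glycolysis then had an adjusted p of 0.0659, heat shock 0.0821 and amino acid response 0.242. The other rises were PFKL and ALDOC in glycolysis, HSPA1B and DNAJB4 in heat shock and ASNS in the amino acid list.

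None of the remaining metabolic and stress lists passed the camera test, and all but the mitochondrially encoded genes held calls in both directions. Among 21 NRF2 targets 4 rose and 5 fell (median −0.15): ABCC3, an efflux transporter, went from 4.77 ± 0.603 to 19.2 ± 1.29 FPKM (SD, n = 3 each), AKR1C3, an aldo-keto reductase, rose by 1.44, and SRXN1, sulfiredoxin, went from 41.3 ± 2.59 to 21.1 ± 2.43 FPKM. Among 23 hypoxia genes 1 rose and 5 fell (median −0.09), with STC2, a secreted glycoprotein, from 114.5 ± 2.59 to 50.6 ± 5.19 FPKM and PFKFB3, which makes an activator of glycolysis, at −1.22. Among 19 fatty acid genes 1 rose and 5 fell (median −0.04), among 23 genes of endoplasmic reticulum chaperones 1 rose and 2 fell (median −0.08), with HYOU1, a chaperone, at −0.90, CANX, calnexin, at −0.52 and DNAJB9, a cochaperone, at 0.57. FASN, fatty acid synthase, had a log2 fold change of −0.78, a call lost without shNC-1 replicate 1 or 2. Among 47 nuclear oxidative phosphorylation genes 2 rose and 3 fell; ATP5MC2, of ATP synthase, rose by 0.96, and the median of 0.12 turned to −0.03 after the length trend was removed. Among 13 mitochondrially encoded genes 0 passed, with a median of 0.01, a mean of 0.03, a camera direction of down and medians of −0.10 to −0.24 under the other scalings. Higher and lower calls adjusted over the list alone were 6 and 5 for NRF2, 1 and 5 for hypoxia, 2 and 7 for fatty acids, 1 and 2 for chaperones, and 0 and 0 for both mitochondrial lists. Camera adjusted p were 0.362, 0.169, 0.290, 0.0821, 0.991 and 0.991. The 29 calls of these lists became 13 without shNC-1 replicate 1 or 2 and 18 without shNC-1 replicate 3. Fatty acid calls were 0 higher and 0 lower without shNC-1 replicate 1 or 2, hypoxia falls numbered 3 without either, chaperone calls were 0 higher and 1 lower without either, leaving HYOU1, and oxidative phosphorylation falls 0 without any 1 of the shNC-1 replicates. With columns scaled to the same total the higher and lower calls were 0 and 5 for hypoxia, 0 and 6 for fatty acids, 1 and 5 for chaperones and 2 and 5 for oxidative phosphorylation. The other calls were TKT, PIR, HMOX1, OSGIN1, GCLM and TXNRD1 among NRF2 targets, MXI1, ANGPTL4, SLC2A1 and BNIP3 in hypoxia, SCD5, ACLY, ACACA, GPAM and ACSL3 in fatty acid synthesis, and COX7B, ATP5MC1, NDUFS1 and SDHB in oxidative phosphorylation.

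Genes of p53 response and apoptosis included strong rises. GDF15, a secreted stress cytokine, rose from 10.2 ± 0.641 to 45.1 ± 9.52 FPKM (SD, n = 3 each). PMAIP1, the NOXA protein, rose by 1.34, BMF by 1.20 and BBC3, the PUMA protein, by 1.00. The last 3 are BH3-only proteins that promote cell death. BMF was low, at a mean of 0.281 FPKM in shNC-1 and 1.99 FPKM in shDLGAP5-1. SESN2, a stress-induced regulator of growth signalling, had a log2 fold change of −0.82, AEN, a nuclease, −0.77, and CYCS, cytochrome c, −0.76. Of 24 p53 targets 5 rose and 4 fell (median 0.16), and of 25 apoptosis genes 7 rose and 2 fell, with a median of 0.03 that turned to −0.08, −0.09, −0.01 and −0.02 with same-total, median-ratio and quantile scaling and the length trend removed. In each list 7 were higher and 4 lower when adjusted over the list alone. Camera gave adjusted p of 0.568 and 0.951, so neither list stood apart from other genes. The 17 calls became 9 without shNC-1 replicate 2, where apoptosis rises numbered 3. The p53 falls numbered 2 without any 1 of the shNC-1 replicates, and apoptosis falls 1 without any 1 library but shDLGAP5-1 replicate 3, leaving CYCS; p53 rises numbered 3 without shNC-1 replicate 1 or shDLGAP5-1 replicate 2, and the apoptosis median was −0.04 and −0.05 without these. With columns scaled to the same total p53 calls became 4 higher and 5 lower and apoptosis calls 5 higher and 5 lower. The other p53 calls were PERP, FDXR and DDB2, higher, and TIGAR and PLK3, lower, and CFLAR, a caspase regulator, was the other apoptosis gene that fell.

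Adhesion and matrix genes changed in opposite directions within each list. SNAI2, a repressor of epithelial genes, went from 29.2 ± 1.16 to 9.12 ± 3.6 FPKM (SD, n = 3 each), PLAUR, the urokinase receptor, had a log2 fold change of −0.96, and FN1, fibronectin, rose from 234 ± 10.6 to 455 ± 60.7 FPKM. JUP, plakoglobin of cell junctions, rose by 1.46 and CLDN1, claudin of tight junctions, by 0.65, while KRT19, a simple epithelial keratin, was at −0.76. COL17A1, a hemidesmosome collagen, had a log2 fold change of −1.45. LTBP3, which stores latent TGF-beta, rose by 1.66, ACTA2, smooth muscle actin, by 1.29, and TAGLN, an actin-binding protein, was at −1.54. Of 20 mesenchymal genes 2 rose and 6 fell (median −0.09), of 11 epithelial adhesion genes 3 rose and 2 fell (median −0.24, mean 0.01, camera down), of 26 collagen and matrix genes 5 rose and 6 fell (median 0.07, mean −0.03, camera down), and of 20 TGF-beta targets 4 rose and 4 fell (median 0.08). The collagen and TGF-beta medians turned negative, −0.02 each, with columns scaled to the same total and were −0.03 each with median-ratio scaling. Relative to the median of all genes they did not turn. Collagen was then at 0.041 as reported and 0.039 and 0.040 under these scalings, and TGF-beta at 0.045, 0.040 and 0.041. Calls adjusted over the list alone were, for higher and lower genes, 2 and 6, 3 and 3, 6 and 8, and 7 and 5. Camera adjusted p were 0.181, 0.735, 0.883 and 0.991. The 29 calls became 18 without shNC-1 replicate 2. Mesenchymal falls numbered 3, 2 and 3 without shNC-1 replicate 1, 2 or 3, collagen rises 3 without any 1 of them, epithelial falls 1 without replicate 1 or 2, and TGF-beta falls 2 without replicate 2. With columns scaled to the same total epithelial calls were 2 higher and 3 lower and collagen calls 3 higher and 7 lower. Other genes in the counts of 5 or fewer were COL6A2, COL4A1, LAMB1, COL7A1, MARVELD2, PMEPA1 and JUNB, higher, and TJP1, CCN2 and ID3, lower.

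Transcription factor genes of the immediate early response also split. JUND rose from 36.9 ± 1.17 to 83.2 ± 7.62 FPKM (SD, n = 3 each), JUNB by 0.94 and KLF4, a zinc finger factor, by 0.81, while DUSP1, a phosphatase that acts on MAP kinases, had a log2 fold change of −1.04. Of 18 immediate early genes 4 rose and 4 fell, and of 22 MAP kinase feedback genes 3 rose and 1 fell; SPRY1, a feedback inhibitor, rose by 0.83, DUSP6 by 0.38 and KCNN4 by 0.65, and DUSP7 was at −0.46. Of these 4 only SPRY1 kept its call in every leave-one-out fit. That of DUSP6 was lost in all 6, and those of KCNN4 and DUSP7 in 5. SPRY1 was low, at a mean of 0.284 FPKM in shNC-1 and 1.29 FPKM in shDLGAP5-1. The counts were the same when adjusted over the list alone. Their medians were 0.11 and 0.04. The first turned to −0.15 without shNC-1 replicate 3 and −0.03 with no filter on low values. The second turned to −0.03 with columns scaled to the same total and −0.05 with median-ratio scaling, which left 0 rises and 3 falls. Relative to the median of all genes the second did not turn, at 0.005 as reported and 0.030 and 0.026 under these scalings. Camera gave adjusted p of 0.991 and 0.934. The 12 calls became 7 without shNC-1 replicate 1 or 2, where immediate early falls numbered 2. The other immediate early calls were NR4A2, higher, and ATF3, JUN and FOSB, lower.

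White blood cell genes stood high in a single library, and markers of other cell types showed smaller peaks in other libraries. In shDLGAP5-1 replicate 3 LYZ stood at 686 FPKM, and PRTN3, AZU1 and CTSG, proteases and a relative from neutrophil granules, at 183, 171 and 51.8 FPKM, genes chosen after their values were seen. The median of 9 granule genes was 39.1 FPKM there, 1.44 in shNC-1 replicate 3, 0.995 in shDLGAP5-1 replicate 1, and 0.374, 0.0504 and 0.0264 in shNC-1 replicates 1 and 2 and shDLGAP5-1 replicate 2. The 18 leukocyte markers summed to 744.3 FPKM in that library and to 8.56 to 32.1 FPKM in the others; the 2 that could be tested, LYZ and CD68, did not pass (adjusted p = 0.430 and 0.930). Fibroblast markers summed to 59.3 FPKM there, 56.1 of it from S100A4, a calcium-binding protein, against 5.07 to 9.17 elsewhere. Of these, 0 of 2 tested genes passed the threshold. Endothelial markers summed to 9.19 FPKM there, 8.45 of it from PECAM1, named after its value was seen, against at most 1.09 elsewhere, with 0 genes tested. Each sum came mostly from 1 gene, so neither shows fibroblasts or endothelial cells in that library. In shNC-1 replicate 2, 9 of 15 detected basal keratinocyte markers had their peak, among them KRT17 at 6.38 and KRT5 at 3.95 FPKM, and in shNC-1 replicate 1 so had 6 of 10 detected fibroblast markers, with COL1A2 at 1.66 and DCN at 1.52 FPKM, genes named after their values were seen. Of 6 basal keratinocyte genes COL17A1 fell and 0 rose (median −0.56, and −0.33 without shNC-1 replicate 2; camera adjusted p = 0.0513), of 4 luminal urothelial genes ELF3, an epithelial transcription factor, rose by 0.99 and 0 fell (median 0.09, and −0.02 with median-ratio scaling; adjusted p = 0.991), and of 5 neuronal genes SNAP25 and MAP2, of synapses and dendrites, rose by 0.57 and 0.78 and 0 fell (median 0.42, and 0.18 without shNC-1 replicate 3; adjusted p = 0.327). The ELF3, SNAP25 and MAP2 calls were lost in leave-one-out fits. SNAP25 and MAP2 were low, at means of 0.525 and 0.497 FPKM in shNC-1 and 1.26 and 1.54 FPKM in shDLGAP5-1. For p adjusted over the list alone, 3 basal genes were lower and 0 higher, 1 luminal gene higher and 1 lower, 2 neuronal genes higher and 0 lower, and 0 fibroblast or leukocyte genes were higher or lower.

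**Figure D3:**
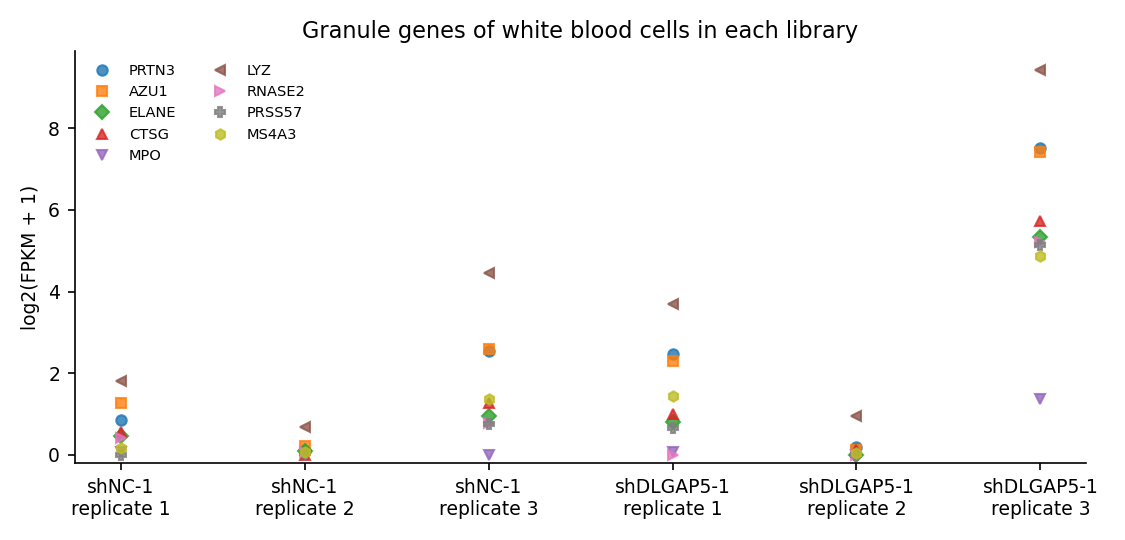
Log2(FPKM + 1) of 9 genes of white blood cell granules in each of the 6 libraries; each marker shape is a gene. In shDLGAP5-1 replicate 3 the median gene is at 39.1 FPKM, and in the other libraries at 1.44 FPKM or lower.

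Transcripts of different length moved apart between libraries of the same group. Genes with a longest transcript up to 1151 bases lay a median of 0.23 above the mean of the 6 libraries on the log2 scale in shDLGAP5-1 replicate 1 and at −0.15 and −0.11 in shNC-1 replicates 1 and 2, and genes over 7350 bases at −0.21, 0.12 and 0.08 in the same libraries. In shNC-1 replicate 3 and shDLGAP5-1 replicates 2 and 3 the short genes lay at 0.01, 0.04 and 0.01, and the long genes at −0.11, −0.02 and 0.14. Across genes, which are not independent replicates, log2 fold change and length had a Spearman correlation of −0.15, with a median log2 fold change of 0.15 in the shortest 10% and −0.05 in the longest 10%.

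**Figure D4:**
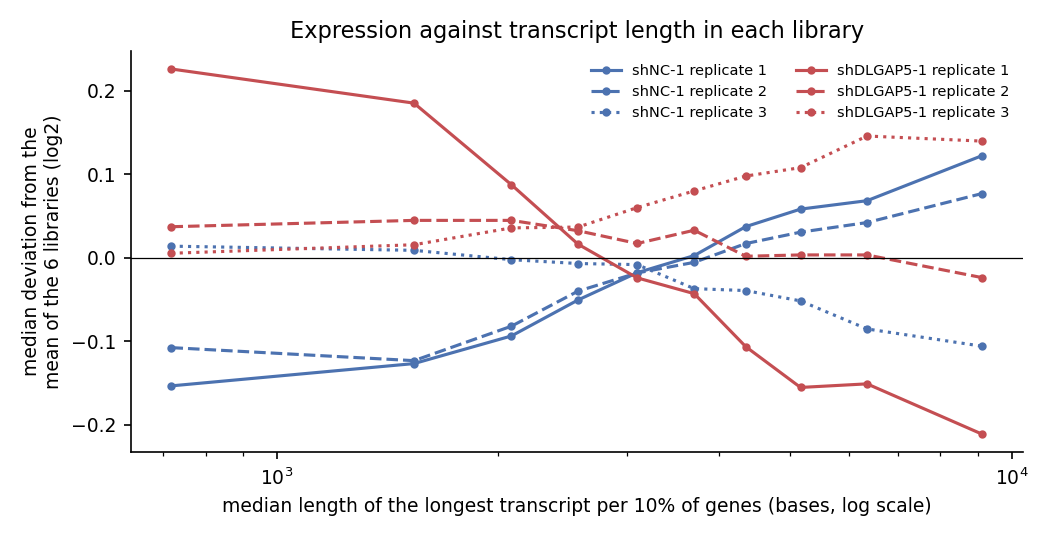
Median deviation from the mean of the 6 libraries (log2) for each 10% of genes ordered by transcript length, against their median length (bases, log axis); each line is a library. From short to long genes shDLGAP5-1 replicate 1 goes from 0.23 to −0.21, and shNC-1 replicate 1 from −0.15 to 0.12.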

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

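Chosen before the data were examined were the pseudocount, the filter of low values, the block, leave-one-out, the minimum fold of 1 and the list tests; the other scalings, the length correction, the 5 FPKM filter, the robust prior, treat and leaving out both doubted libraries were chosen after seeing the data. No called result reversed. DLGAP5 stayed past the threshold in every fit run, between −2.58 and −2.19 in leave-one-out fits, and E2F1 in none. Of 3155 changed genes, those called again ranged from 328 with treat to 3141 with the robust prior, and 0 changed sign in any fit. Changed, higher and lower genes numbered 584, 406 and 178 with an absolute log2 fold change of at least 1 and 328, 242 and 86 with treat, which ask for larger changes, and 1565, 955 and 610 without shDLGAP5-1 replicates 1 and 3, which leaves 1 shDLGAP5-1 sample, assumed to vary like the controls. Leave-one-out fits, with fewer samples too, gave 1335 to 3141 changed, 863 to 1777 higher and 472 to 1364 lower. Without a filter, with 31433 genes tested, 2071 changed and 769 were lower. With at least 5 FPKM, with 8781 genes tested, 1168 were higher, or 52% of the changed genes. Same-total scaling gave 1261 higher, median-ratio scaling 1917 lower and the length correction 1890 lower; the cause was not tested.

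The replicate block gave 1464 changed, 951 higher and 513 lower, and with the length correction 1171 higher. The deviations gave no sign that the numbers pair the samples. Those of same-numbered samples correlated at −0.155, 0.021 and −0.157, and 0 of 6 samples correlated best with its own number. The deviations also carry the length trend of each library, so they cannot exclude a shared culture or day. The block moved the amino acid (adjusted p = 0.0519) and heat shock (0.0543) lists above the threshold of 0.05, so that neither passed, and changed no other list call.

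With the preset correlation 12 lists passed, and 9 to 16 in leave-one-out fits. With an estimated correlation 1 passed. The estimates for cholesterol and NF-kB, −0.0045 and −0.0254, were under the preset 0.01. They argue against a higher correlation as the reason why these lists no longer passed. The other lists that no longer passed had estimates above 0.01. The adjusted p with an estimated correlation were 0.0904 for mitosis, spindle partners, cholesterol and ribosome biogenesis, 0.218 for antigen presentation, 0.171 for NF-kB, 0.408 for YAP and for amino acid response, 0.340 for glycolysis, 0.303 for heat shock and 0.709 for ribosomal proteins, for which fry gave 0.101. In leave-one-out fits adjusted p ran from 0.00305 to 0.0722 for NF-kB, 0.0326 to 0.153 for amino acid response and 0.0264 to 0.1002 for heat shock. With at least 5 FPKM these 3 lists had 0.0732, 0.179 and 0.1004, with median-ratio scaling 0.0546, 0.0508 and 0.0546, and with quantile normalization 0.0759, 0.310 and 0.0901. Without shDLGAP5-1 replicates 1 and 3, where the spread comes from the controls alone, amino acid response had 0.242, heat shock 0.0821 and glycolysis 0.0659. The cause was not tested. Over the 19 camera alternatives of each list, adjusted p ranged from 0.00173 to 0.171 for NF-kB, 0.0105 to 0.408 for amino acid response, 0.00613 to 0.303 for heat shock and 7.12e-05 to 0.340 for glycolysis. Of 154 other named genes 118 passed, 91 of them in every leave-one-out fit and 85 in every alternative other than treat.

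Not run, because they need counts, were the planned count tests, their size factors and the 50-count filter. Depth, estimated at 13700000 to 27500000 fragments, limits genes of low level. The simulated test with 3 libraries per group recovered 8.1% of genes changed by a log2 fold of 0.5. It held only 200 changed genes per run, so this share does not measure recovery in the data.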

Other observations

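The gene groups of this first paragraph were chosen after the data were seen. Complement and acute phase genes were higher in shDLGAP5-1 cells: of 9 tested members 8 rose and 0 fell, with a median log2 fold change of 1.41. C3, the central complement component, went from 16.2 ± 1.59 to 46.2 ± 6.57 FPKM (SD, n = 3 each), LCN2, an iron-sequestering lipocalin, from 3.55 ± 0.664 to 17.5 ± 1.33 FPKM, and SAA1, an acute phase protein, rose by 2.09. C1R and C1S, proteases of the classical pathway, rose by 1.29 and 1.41. The mitochondrial ribosomal RNAs MT-RNR1 and MT-RNR2 rose by 0.84 and 1.43, the latter from 2079 ± 100.6 to 5677 ± 983.7 FPKM, while 0 of 13 mitochondrially encoded protein genes passed. Of 5 metallothionein genes 3 rose and 0 fell, MT1F by 1.64, MT2A by 0.67 and MT1X by 0.55. The alpha-arrestin genes ARRDC3 and ARRDC4, relatives of TXNIP, rose by 1.17 and 0.91.

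The tests of white blood cell transcripts, of the share of dividing cells and of the length correction were chosen after the data were seen; those of other splits and of the number of hairpins were planned.

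White blood cell transcripts stood out in shDLGAP5-1 replicate 3. A response of T24 cells to the hairpin, which is argued against if shared by the shDLGAP5-1 libraries, would raise such genes in replicates 1 and 2 as well. The leukocyte markers fixed beforehand, without LYZ, summed to 6.81 and 8.45 FPKM there, against 7.61 to 11.02 FPKM in the controls and 58.3 FPKM in replicate 3. Reads or RNA from a white blood cell source may account for them: 9 of 12 detected leukocyte markers, a list fixed beforehand of which 0 of 18 genes are in another list fixed then, peaked there, with CD4 at 11.7, TYROBP at 11.2 and PTPRC at 7.03 FPKM. LYZ is both in that list and among the granule genes that prompted the test. Peaks in 1 library also occurred for 9 of 15 detected basal keratinocyte markers in shNC-1 replicate 2, at lower levels (KRT17 at 6.38 FPKM), so the count alone is weaker than the levels. MPO, a granule gene, was only at 1.57 FPKM there beside LYZ at 686. Whether the source was cells, RNA or reads of another library was not tested.

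Interferon response genes were higher in shDLGAP5-1. The length trend is argued against as their whole cause, since the list median was 1.22 after its removal, and so are white blood cell reads, since it was 1.29 in shDLGAP5-1 replicate 2, which has the lowest granule median. With 1 hairpin against DLGAP5, an effect of that hairpin other than loss of DLGAP5 cannot be told apart from an effect of DLGAP5, because both would be the same in these libraries. A response to DLGAP5 loss is a hypothesis that a second hairpin could test.

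Mitotic genes were lower in shDLGAP5-1. The length trend is argued against as the whole cause, since the list median was −0.68 after its removal. A smaller share of dividing cells as the whole cause would lower S-phase genes about as much only if both lists depend on it alike. That was not tested, so the comparison of the lists cannot decide. The lower quartile of the S-phase list was −0.28, above the mitosis median of −0.62, and remained above it in every alternative. What lowers the mitotic genes is open: the phases of the cells were not measured, and no other hairpin against DLGAP5 is among these libraries.

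As to the count of 3155 changed genes, 1 of the 10 splits of the 6 libraries into 3 and 3, the real one, gave that many, and the highest other split gave 3; 10 splits are too few for a share under 0.05.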
